A study of Mus musculus with 4 samples.

How the data were processed

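RNA from mouse brain at postnatal day 1 was profiled in 4 libraries, 2 labelled WT and 2 labelled CIC knockout. Per the labels' protocols, total RNA was purified on silica columns with DNase digestion and made into Illumina libraries; the selection of RNA and the strandedness are not given in the sources used here. The submitters' processing notes name bcl2fastq 2.17, cutadapt, TopHat2 2.0.11, Cufflinks 2.1.1 and the mm9 genome build, without their order or settings. The deposited table holds 1 FPKM value (fragments scaled by transcript length and by mapped fragments) per gene row and library. The unit was inferred from the tools named in the submitters' processing notes and from the values. The table had 20793 rows with 20462 gene names, 188 of them on several rows, and each row was tested on its own. Coordinates are those of the deposited table in mm9 with the start raised by 1 to count from 1. Only 131 of 19176 names that matched a GRCm38 annotation lay at the same place there, so no coordinate was taken from that build.

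FPKM values are not counts, and no count model was used. Values were analysed as log2(FPKM + 1) for the 12703 rows with a mean FPKM over the 4 libraries of 1 or more. Log2 differences are on that scale, which understates the change of low genes. Knockout was compared with WT in limma 3.58.1 under R 4.3.3 with lmFit and eBayes (trend and robust off), 2 libraries against 2, no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.63 prior degrees of freedom. An exact permutation test of 2 against 2 cannot give a two-sided p below 0.333, so significance rests on the spread that limma shares across genes.

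Before the data were examined, 28 lists with 340 genes and no gene in more than 1 list were fixed: CIC target and ERK feedback genes, chosen from general knowledge of CIC, its partners, and markers of brain cell types, regions, blood, stress and sex. Of these, 25 lists had at least 3 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with the rotation test fry, each adjusted over the lists. With the preset correlation 7 lists were called higher and 8 lower. With the estimated correlation 0 were called, the lowest adjusted p being 0.516. Fry called 3 lists (CIC target, astrocyte and immediate early genes). These 3 lists and the CIC partners had estimated correlations below the preset. In the other lists called with the preset, estimates ran from 0.111 (cortical layer) to 0.999 (sex-linked). The preset may overstate those calls. Membership in the CIC target list among genes called higher was tested with Fisher's exact test. The genes named are Cic, up to 10 genes with the largest change past the threshold in each direction with no overlap between groups, the members of each list past the threshold or else the 2 with the largest change, and every CIC target list member past it; other names were chosen after their values were seen, among them further members of the lists and Tcf7l2, Hmox1, En2 and Dag1. A gene that the rule names is not reported here.

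The calculation was tested on simulated data with 12703 genes and 2 libraries against 2. Changed genes were drawn only from well-expressed rows. Noise was independent between genes and of equal size in all libraries, whereas the real knockout pair varied more than the WT pair. The rates and list calls below therefore need not hold for the real comparison. Of 100 genes changed by a log2 value of 1, 51 were called, and of 100 changed by a log2 value of 2, 91 were called, with 3 unchanged genes called and 5.25% of unchanged genes at an unadjusted p under 0.05. The CIC target list moved by a log2 value of 1 was called by camera with the preset correlation and not with the estimated correlation. By either, 0 of the other lists were called. A list that misses a call with the estimated correlation may therefore still have shifted. The simulation does not speak to lists with a high estimated correlation, since its noise was independent between genes.

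Total depth is unknown because the table gives no counts. Relative depth was taken from rows above 0 and under 0.15 FPKM in both WT A and the library compared with it. The most common ratio of their values, within a limited range, was read as that of rows with equal fragment numbers. This assumption was not tested. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean FPKM of 5), a rescaling to equal medians, limma's trend option, the replicate letter as a block, leaving out each library, and leaving out blood, sex-linked and mitochondrial lists. Leaving out the rows with a listed 0 and weighting the libraries by their quality were added after seeing the data. The quality weights were 2.74 for each WT library and 0.365 for each knockout library. Libraries of a pair get equal weights by construction in this design, so the weights could not single out knockout B. Marker lists for caudal brain, hypothalamus and cortex were also added then, and their log2 ratios were taken with a pseudocount of 0.1 and repeated with 1.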

Results

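CIC (capicua) is an HMG-box transcriptional repressor that ERK signalling relieves, and the series asked what its loss does to the developing mouse brain. Brain RNA from postnatal day 1 was profiled by RNA-seq in 2 wild-type (WT) libraries and 2 CIC knockout libraries, each pair carrying the replicate letters A and B. In the knockout, Cre recombinase driven by Nestin regulatory sequence, active in neural progenitors, acts on a loxP-flanked Cic allele. The labels of the WT animals conflict: their titles describe Cre-negative animals on a floxed background, and their genotype field gives Nes-Cre with an unmodified Cic gene. Groups were taken from the description field, which names both plainly. Each library was given as FPKM for 20793 gene rows, with column sums between 440005 and 449559. Total read depth is unknown. The most common ratios of low values to those of WT A put relative depth at 1 for WT A, 1.20 for WT B, 1.22 for knockout A and 1.03 for knockout B. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples.

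Cic RNA was lower in both knockout libraries than in either WT library. Its locus (mm9, chromosome 7, 26067198 to 26079167) had 53.8 ± 3.57 FPKM in WT and 20.7 ± 2.24 FPKM in knockout brain (SD, n = 2 each). The WT libraries had 51.3 and 56.4 FPKM and the knockout libraries 19.1 and 22.2 FPKM. The log2 difference was -1.34 ± 0.12 (SE), and limma's adjusted p over all genes was 0.213, short of the 0.05 threshold. Without knockout replicate B the adjusted p was 0.0254, and without knockout replicate A it was 0.00486. Each of these fits takes its spread from the WT pair alone (SE 0.09) and assumes that the lone knockout library varies like it. Without WT A or WT B the adjusted p was 0.733 and 0.665. The FPKM covers the whole gene, and which exons were deleted is not given in the sources used here, so RNA from outside the deleted part may be included in it.

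Etv4, Spred3 and Mid1 rose in CIC knockout brain. Etv4, an ETS transcription factor and a known direct CIC target (chromosome 11, 101631056 to 101646624), went from 7.63 ± 0.295 to 48.2 ± 4.48 FPKM, a log2 change of 2.51 ± 0.11 (SE) with limma's adjusted p of 0.0195. Spred3, a Sprouty-related inhibitor of Ras-ERK signalling (chromosome 7, 29943848 to 29953666), went from 8.62 ± 0.726 to 39.3 ± 1.55 FPKM. Its log2 change was 2.07 ± 0.11, with limma's adjusted p of 0.0307. Mid1, a microtubule-associated ubiquitin ligase (X chromosome, 166123179 to 166428729) whose 3′ part is pseudoautosomal and repetitive in common laboratory mice, went from 13.7 ± 0.0374 to 73.6 ± 10.7 FPKM. Its log2 change was 2.33 ± 0.13, with limma's adjusted p of 0.0408. Each of these values is a mean ± SD over 2 libraries, and both knockout libraries lay above both WT libraries. None of the 3 genes was called without WT A (adjusted p of 0.0845 for Etv4, 0.184 for Spred3 and 0.165 for Mid1), without WT B (0.0735, 0.111 and 0.117) or with no filter on low values (0.293 for each). With a pseudocount of 0.1 the calls of Spred3 (0.0714) and Mid1 (0.0918) ended. Without WT A the log2 changes of Etv4, Spred3 and Mid1 were 2.54, 1.99 and 2.34, and without WT B 2.47, 2.15 and 2.33. In both of these fits their SEs were larger, at 0.216, 0.207 and 0.232.

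The 3 genes called lower were all listed at exactly 0 in both knockout libraries. Prkar1b, a regulatory subunit of protein kinase A, had 169 and 167 FPKM in the WT libraries. Actr3, a core subunit of the actin-nucleating Arp2/3 complex, had 123 and 121 FPKM there, and Papd5, a non-canonical poly(A) polymerase, had 14.5 FPKM in each. Exact zeros beside high values were not limited to these genes or to the knockout. In all, 13 gene rows were at 0 in at least 1 library and at 10 FPKM or more in another. There were 2 such zeros in each WT library, 9 in knockout A and 5 in knockout B. Dag1, which encodes dystroglycan, was listed at 0 in WT A and at 45.2 FPKM in WT B. A listed 0 can therefore be a failed estimate, and no fold change is given for these genes.

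Across 12703 tested genes, limma called 3 genes higher and 3 lower in the knockout. At an unadjusted p under 0.05 there were 1290 genes (10.2%), 840 higher and 450 lower. Both knockout libraries lay on the same side of both WT libraries for 48.9% of genes, against 33.3% by chance for 2 against 2. When the 13 rows with a listed 0 were left out, an alternative added after seeing the data, limma called 0 genes. The adjusted p values were then 0.0688 for Etv4, 0.0688 for Spred3 and 0.0719 for Mid1, because the adjustment ranks the 3 zero-valued genes first in the full set. Without knockout replicate B, which stood apart from the other libraries, 16 genes were higher and 11 lower. Without knockout replicate A, 2269 were higher and 2036 lower. In both of these fits the lone knockout library was assumed to vary like the WT pair. Without WT A, 1 gene (Avp) was higher and 3 were lower. Without WT B, 3 were higher (Dag1, Zfp266 and Ttr, the former pair listed at 0 in WT A) and 4 lower. Etv4, Spred3 and Mid1 were thus called in neither.

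The list of CIC target and ERK feedback genes, fixed before the data were examined, was higher in knockout brain, with a median log2 difference of 0.34. Camera called it with a preset correlation (adjusted p = 8.49e-09) and not with an estimated correlation (adjusted p = 0.516), with which 0 of the 25 tested lists were called. The estimated correlation was -0.035, below the preset 0.01. In the simulation, this list moved by a log2 value of 1 was also missed that way. The missing call therefore does not argue against a shift of the list. Of its 22 genes 20 were measured, and 2 (Etv4 and Spred3) rose over all genes tested. Adjusted over the list alone, 11 were higher and 1 was lower. Vgf, which encodes a secreted neuropeptide precursor, had 15.0 ± 1.55 FPKM in WT and 68.8 ± 15.2 FPKM in knockout brain, and the ETS factor Etv5 had 18.4 ± 0.340 and 57.7 ± 6.99 FPKM (SD, n = 2 each). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, had 2.32 ± 0.204 and 8.80 ± 1.79 FPKM. The MAP kinase phosphatase gene Dusp4 had 28.0 ± 0.840 and 56.4 ± 1.60 FPKM, and the neuronal adaptor gene Shc3 had 16.8 ± 0.663 and 29.8 ± 0.354 FPKM. Maff (log2 difference 1.10 ± 0.16, SE), Plk3 (0.75 ± 0.13), Spred1 (0.37 ± 0.11) and Spred2 (0.31 ± 0.10) made up the rest of the 11. Mycn, a proto-oncogene of neural progenitors, was the member on the lower side, with 36.5 ± 2.30 FPKM in WT and 26.0 ± 1.86 FPKM in knockout brain. Without WT A or without WT B, 9 members were higher and 0 lower adjusted over the list alone, and without either knockout library 13 were higher and 2 lower.

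Other members of that list differed little or moved differently in the 2 knockout libraries. Dusp6, Spry1, Spry2 and Ccnd1, encoding a MAP kinase phosphatase, Sprouty inhibitors and cyclin D1, had log2 differences of 0.24 ± 0.10, 0.20 ± 0.13, -0.13 ± 0.12 and -0.02 ± 0.13 (SE). The ETS factor Etv1 was 0.54 above the WT mean in knockout A and lay at -0.17 from it in knockout B. For the whole list the rotation test fry gave an adjusted p of 0.00475 for a shift in 1 direction. By Fisher's exact test (two-sided), 2 of the 3 genes called higher belonged to the 20 listed genes among 12703 tested, p = 7.06e-06. With the rows listed at 0 left out, limma called 0 genes, so this test could not be run. Genes are not independent replicates, and with either WT library left out 0 of the called genes were in the list.

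**Figure D1:**
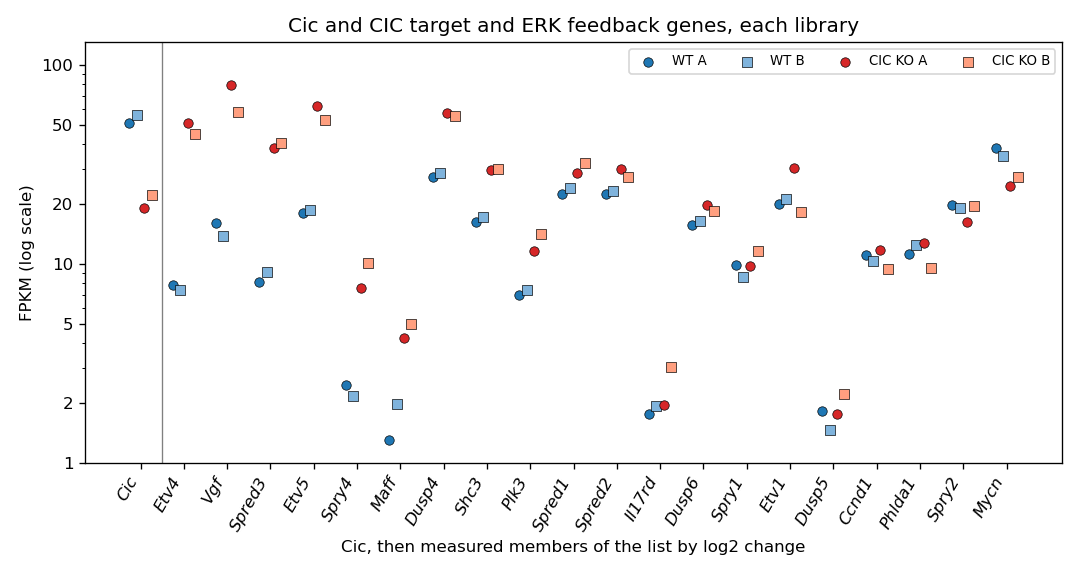
FPKM on a log axis of Cic, left of the grey line, and of the 20 measured CIC target and ERK feedback genes in each of the 4 libraries, ordered by log2 difference; circles are replicate A, squares replicate B, blues WT and reds CIC knockout. Etv4 sits at 7.84 and 7.43 FPKM in WT and at 51.4 and 45.0 FPKM in knockout brain, while Cic sits at 51.3 and 56.4 FPKM in WT and at 19.1 and 22.2 FPKM in knockout brain.

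Genes of cortical projection neurons were lower in the knockout libraries. In the cortical layer list, 13 of 13 genes were measured and 10 lay below both WT libraries in both knockout libraries. None passed over all genes, and adjusted over the list alone 4 were lower. Mef2c, a transcription factor of maturing excitatory neurons, had 135 ± 3.73 FPKM in WT and 65.3 ± 20.8 FPKM in knockout brain (SD, n = 2 each). Its log2 difference was -1.07 ± 0.23 (SE), with limma's adjusted p of 0.417. The POU factor gene Pou3f3 had 82.2 ± 2.84 and 60.8 ± 4.67 FPKM, and the orphan nuclear receptor gene Rorb had 2.83 ± 0.0689 and 1.87 ± 0.1998 FPKM. Foxp2, a marker of deep-layer neurons, was instead at 13.3 ± 0.334 and 16.0 ± 0.0628 FPKM, and Cux1 had a log2 difference of -0.01. The list median was -0.41, with an adjusted p of 5.66e-05 by camera and an adjusted p = 0.536 with an estimated correlation. The list medians were -0.23 in knockout A and -0.34 in knockout B, which stood apart from the other libraries. A separate set of 13 cortex markers, added after the first results were seen, had median log2 ratios to WT of -0.26 and -0.32 on the same scale.

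Other neuronal lists were called lower by camera with the preset correlation alone and with smaller medians, and for several of them knockout B carried most of the difference. Excitatory synapse genes had a median log2 difference of -0.26 (13 measured, 0 passed; camera adjusted p = 0.00679, adjusted p = 0.536 with an estimated correlation). The vesicular glutamate transporter gene Slc17a7 had 45.4 and 50.3 FPKM in WT, 42.2 in knockout A and 10.4 in knockout B. Neurogranin (Nrgn) had 143 and 139 FPKM in WT, 140 in knockout A and 46.1 in knockout B. The other vesicular glutamate transporter gene of the list, Slc17a6, went the opposite way, with 15.2 and 14.5 FPKM in WT, 16.6 in knockout A and 42.1 in knockout B. The list medians were -0.02 in knockout A and -0.56 in knockout B, and without knockout B the camera call ended (adjusted p = 0.249). Pan-neuronal genes had a median of -0.10 (18 measured, 0 passed; camera adjusted p = 0.0249, adjusted p = 0.536 with an estimated correlation). The neuronal bHLH genes Neurod6 (210 ± 5.95 FPKM in WT, 119 ± 44.0 in knockout brain) and Neurod2 (85.6 ± 0.689 and 54.8 ± 6.97 FPKM) differed most. Other members were higher: the neurofilament gene Nefl had 38.1 and 31.5 FPKM in WT, 35.7 in knockout A and 82.1 in knockout B, and the synaptic vesicle gene Syp had 124 ± 6.19 FPKM in WT and 150 ± 5.07 in knockout brain. The pan-neuronal call also ended without knockout B, where the list median was -0.016. Without knockout A the median was -0.22. Intermediate progenitor genes had a median of -0.20 (7 measured, 0 passed; camera adjusted p = 0.0202, adjusted p = 0.536 with an estimated correlation). Insm1 was at 24.9 ± 0.294 and 17.2 ± 2.55 FPKM and Neurog2 at 3.79 ± 0.487 and 2.67 ± 0.341 FPKM. The call of this list ended without knockout A (adjusted p = 0.307), with no filter on low values (0.0647) and with a mean FPKM of 5 or more (0.0640), and without WT A its median was -0.09.

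Axon guidance and adhesion genes (20 measured, 0 passed) had a median log2 difference of -0.12, immediate early genes (10 measured, 0 passed) -0.18, and CIC partners and corepressors (13 measured, 0 passed) -0.10. Their camera adjusted p values were 0.0472, 0.0277 and 0.0472, each with an adjusted p = 0.536 with an estimated correlation, and each call ended without knockout B (adjusted p of 0.313, 0.0535 and 0.098). Leaving out WT B (0.0607 and 0.0923) ended the first and last of these calls, and leaving out knockout A (0.15 and 0.0631) the second and last. The axon guidance and partner calls also ended with a pseudocount of 0.1 (0.0566 and 0.0553), no filter (0.0647 for both) and a mean FPKM of 5 or more (0.0515 and 0.124). The axon guidance call ended with libraries rescaled to a median log2 ratio of 0 (0.0675). The immediate early call ended with a mean FPKM of 5 or more (0.0655) and with libraries weighted by quality (0.0559). Without knockout B the medians of the axon guidance, immediate early and partner lists were -0.031, -0.106 and -0.064. The adhesion gene Cntn2 had 53.6 ± 1.87 FPKM in WT and 26.7 ± 7.95 in knockout brain, whereas the guidance ligand gene Ntn1 had 7.11 ± 0.0499 and 13.6 ± 3.16 FPKM. Among immediate early genes, Egr3 had 6.83 ± 1.09 and 3.98 ± 3.04 FPKM and Arc had 2.16 ± 0.668 and 1.28 ± 0.117 FPKM, whereas Fos had 2.39 ± 0.306 and 3.70 ± 1.13 FPKM. The histone deacetylase gene Hdac2 (116 ± 3.42 and 93.0 ± 17.8 FPKM) and the chromatin remodeller gene Smarca4 (62.9 ± 0.312 and 50.8 ± 11.04 FPKM) differed most among the partners.

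Astrocyte and choroid plexus genes were higher in the knockout libraries. Of 11 measured astrocyte genes 8 lay above both WT libraries in both knockout libraries. None passed over all genes, and 1 was higher adjusted over the list alone. This was Apoe, which encodes the main brain apolipoprotein (212 ± 16.2 FPKM in WT and 346 ± 46.3 in knockout brain; SD, n = 2 each). Fgfr3 had 10.9 ± 0.453 and 16.4 ± 2.35 FPKM. The median log2 difference was 0.28 (camera adjusted p = 0.000449, adjusted p = 0.536 with an estimated correlation), and without knockout A the call ended (adjusted p = 0.052). Of 8 measured choroid plexus and ependyma genes 0 passed over all genes and 7 were higher adjusted over the list alone. The median was 1.27 (camera adjusted p = 0.000449, adjusted p = 0.536 with an estimated correlation). Ttr, the transthyretin gene that dominates choroid plexus RNA, had 144 and 475 FPKM in the WT libraries and 951 and 1005 FPKM in the knockout libraries, so that the WT libraries themselves differed. The list median of WT B minus WT A was 0.74, and the median difference was 0.75 without WT A and 0.70 with a pseudocount of 5. The homeobox gene Otx2 had 0.838 and 1.53 FPKM in WT, 2.75 in knockout A and 11.2 in knockout B.

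The remaining lists called higher, by camera with the preset correlation alone, were cerebellum, microglia and macrophage, meninges and fibroblast, and integrated stress response genes, with no member past the test over all genes. Cerebellar genes had a median log2 difference of 1.23 (8 measured; camera adjusted p = 0.00584, adjusted p = 0.536 with an estimated correlation) and 3 were higher adjusted over the list alone. These were the zinc finger genes Zic1 (11.3 ± 2.48 FPKM in WT, 45.2 ± 23.5 in knockout brain), Zic2 (11.99 ± 0.160 and 30.7 ± 12.5) and Zic4 (2.61 ± 0.396 and 10.5 ± 3.29). In knockout A, Zic1 (28.6 FPKM) and Zic4 (8.16 FPKM) lay above both WT libraries. The list member En2 was at 0 there and the list median was 0.13. Microglial genes had a median of 0.44 (12 measured; camera adjusted p = 0.0213, adjusted p = 0.536 with an estimated correlation). The complement gene C1qb was at 18.8 ± 3.16 and 31.7 ± 10.2 FPKM and the lysosomal gene Cd68 at 4.35 ± 0.522 and 8.74 ± 5.93 FPKM. Meningeal genes had a median of 0.31 (9 measured; camera adjusted p = 0.0213, adjusted p = 0.536 with an estimated correlation). The collagen genes Col1a1 (8.26 ± 1.75 and 16.1 ± 5.56 FPKM) and Col1a2 (21.9 ± 6.41 and 33.2 ± 4.997 FPKM) differed most. Integrated stress response genes had a median of 0.31 (10 measured; camera adjusted p = 0.0251, adjusted p = 0.54 with an estimated correlation). Sesn2 was at 2.48 and 2.45 FPKM in WT, 3.58 in knockout A and 13.9 in knockout B, and Chac1 was at 2.96 ± 0.104 and 6.60 ± 3.74 FPKM. Without knockout B the cerebellar, microglial and stress response calls ended (adjusted p of 0.0535, 0.158 and 0.629), and without WT A or knockout A the meningeal call ended (0.157 and 0.489). With no filter the cerebellar, microglial, meningeal and stress response calls ended (0.0647, 0.102, 0.0647 and 0.102), and with a mean FPKM of 5 or more the meningeal and stress response calls ended (0.0624 and 0.0655). Without WT A the microglial, meningeal and stress response medians were 0.28, 0.10 and 0.19. Without knockout B the cerebellar, microglial and stress response medians were 0.13, 0.20 and 0.018.

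**Figure D2:**
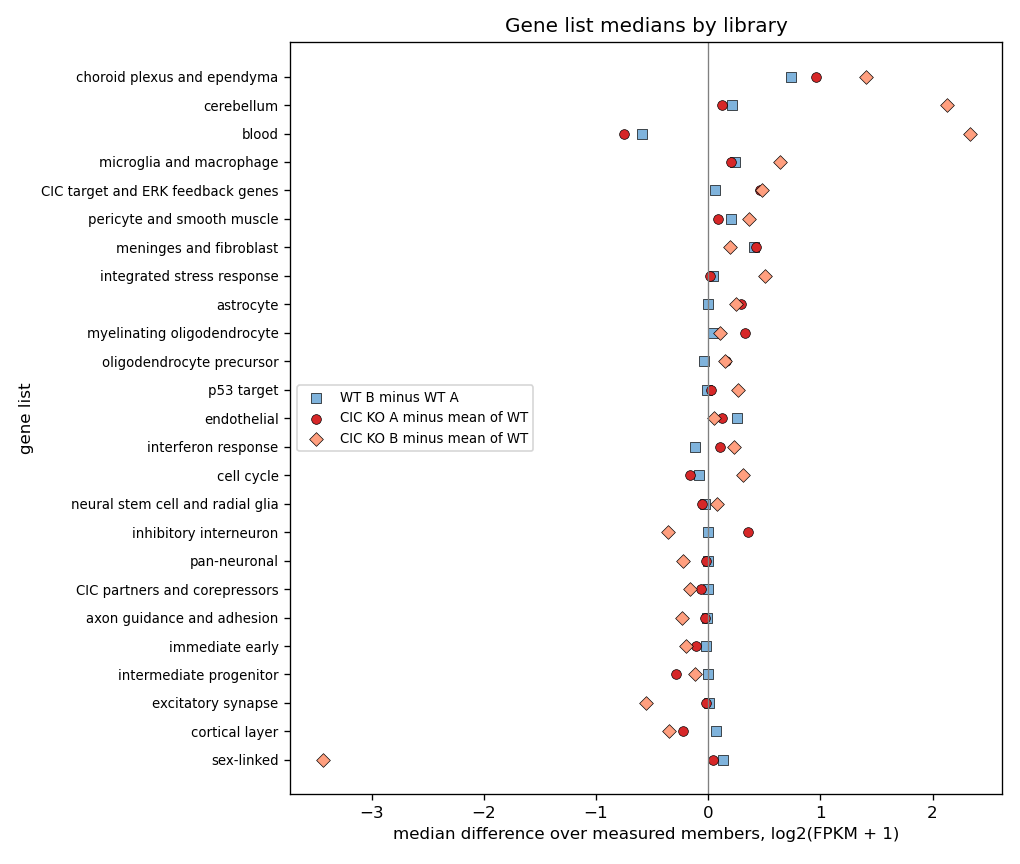
Median difference in log2(FPKM + 1) over the measured members of the 25 tested gene lists, for knockout A (red circles) and knockout B (orange diamonds) against the mean of the WT libraries and for WT B against WT A (blue squares). The CIC target list lies at 0.46 in knockout A and 0.48 in knockout B with 0.06 between the WT libraries, whereas cerebellar genes lie at 0.13 and 2.13.

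Lists of neural stem cells and radial glia, cycling cells, interneurons and the oligodendrocyte lineage were not called, and no member passed over all genes. Neural stem cell and radial glia genes (17 measured) had a median log2 difference of 0.04. Nes was at 11.1 ± 0.146 FPKM in WT and 7.42 ± 0.824 in knockout brain and Id4 at 27.8 ± 5.07 and 44.6 ± 11.3 FPKM. Cell cycle genes (16 measured) had a median of 0.06, with Ccnd2 at 36.4 ± 0.453 and 29.1 ± 2.24 FPKM and Birc5 at 6.64 ± 0.626 and 8.83 ± 2.72 FPKM. For these 2 lists the mean was also above 0 while camera placed them on the lower side (adjusted p of 0.617 and 0.751). Inhibitory interneuron genes (13 measured) had a median of -0.04 and a mean of 0.08, and camera placed them on the higher side (adjusted p = 0.633). Gad1, which encodes the GABA-synthesising enzyme, had 50.8 ± 2.92 and 73.8 ± 4.97 FPKM, and Calb2 22.5 ± 2.13 and 41.0 ± 16.9 FPKM. The interneuron median was 0.35 in knockout A and -0.36 in knockout B, and without knockout B camera called the list higher (adjusted p = 2.39e-05). The cell cycle median was -0.16 in knockout A and 0.31 in knockout B; camera called it lower without knockout B (adjusted p = 4.26e-05) and higher without knockout A (adjusted p = 0.024). Oligodendrocyte precursor genes (11 measured) had a median of 0.17 (camera adjusted p = 0.159). Bcan was at 34.3 ± 1.18 and 43.6 ± 0.624 FPKM and Nkx2-2 at 0.822 ± 0.0453 and 2.23 ± 1.09 FPKM. Myelinating oligodendrocyte genes (7 measured) had a median of 0.24 (camera adjusted p = 0.16). Mbp was at 12.5 ± 0.0226 and 16.4 ± 4.06 FPKM and Cldn11 at 8.76 ± 1.88 and 11.5 ± 2.91 FPKM. Without knockout B both oligodendrocyte lists were called higher (adjusted p of 0.0466 and 0.013), and without WT B the myelinating list was called higher (adjusted p = 0.0274).

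Vascular, p53 and interferon lists were also not called. Endothelial genes (10 measured) had a median log2 difference of 0.10 (camera adjusted p = 0.306). The glucose transporter gene Slc2a1 was at 26.3 and 60.7 FPKM in WT and 64.8 and 59.0 FPKM in knockout brain, and Slco1c1 was at 26.8 ± 0.823 and 18.4 ± 12.8 FPKM. Pericyte and smooth muscle genes (7 measured) had a median of 0.32 (camera adjusted p = 0.16). Without WT A this median was 0.15, and without knockout B it was 0.084. The smooth muscle actin gene Acta2 was at 2.04 ± 0.486 and 5.19 ± 2.45 FPKM and Tagln at 2.86 ± 0.446 and 4.50 ± 0.8004 FPKM. Without WT B both vascular lists were called higher (adjusted p of 0.00879 and 0.00712). The p53 target list (10 measured) had a median of 0.13 (camera adjusted p = 0.241). The cell cycle inhibitor gene Cdkn1a was at 13.4 ± 0.983 and 24.6 ± 6.83 FPKM and Sesn1 at 19.7 ± 2.18 and 24.8 ± 1.01 FPKM. Interferon response genes (5 measured) had a median of 0.08 (camera adjusted p = 0.241). Ifitm3 was at 15.9 ± 0.511 and 20.8 ± 1.90 FPKM and Bst2 at 3.96 ± 0.480 and 4.69 ± 0.511 FPKM. Mitochondrially encoded genes were not analysed here.

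Genes of the hindbrain, blood and Y chromosome set knockout B apart from the other 3 libraries. The segment identity genes Hoxa5 and Hoxb5 had 6.09 and 5.38 FPKM in knockout B and at most 0.0389 and 0.0184 FPKM elsewhere. They were the 2 measured members of the hindbrain and spinal Hox list, too few for camera. The midbrain-hindbrain gene En2 had 5.27 FPKM in knockout B and at most 0.115 FPKM elsewhere, and Tcf7l2, abundant in thalamus and midbrain, had 2.14 and 2.34 FPKM in WT, 5.17 in knockout A and 56.0 in knockout B. Beta-globin Hbb-b2 had 92.8 and 58.6 FPKM in WT, 90.0 in knockout A and 494 in knockout B, while both Hba-a1 loci were listed at 0 in knockout A. The blood list (5 measured, 0 passed, camera adjusted p = 0.633) had a median of 0.45 and a mean of -0.16. With the rows listed at 0 left out, the median of the blood list was 1.33 (camera adjusted p = 0.189). Its median was 2.33 without knockout A (camera adjusted p = 0.00741) and -0.75 without knockout B, which leaves the alpha-globin zeros of knockout A (camera adjusted p = 0.0174). Hmox1, the heme-degrading heme oxygenase gene, had 5.17 and 4.54 FPKM in WT, 5.79 in knockout A and 194 in knockout B.

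The Y-linked gene Ddx3y had 14.9 and 17.0 FPKM in WT, 17.0 in knockout A and 0.0173 in knockout B, and Eif2s3y had 24.3, 34.6, 29.1 and 0.0150 FPKM in the same order. The sex-linked list (4 measured, 0 passed) had a median log2 difference of -1.70 (camera adjusted p = 0.0472, adjusted p = 0.536 with an estimated correlation), and without knockout B its median was 0.04. This call ended with a pseudocount of 0.1 (0.0553), with no filter (0.108) and with libraries rescaled to a median log2 ratio of 0 (0.0675). Among all tested genes, 201 differed at least 2-fold between knockout A and knockout B, against 32 between WT A and WT B. Of the pituitary and hypothalamus list 1 of 12 genes was measured, too few for camera: the vasopressin gene Avp had 4.36 and 0.281 FPKM in WT and 16.3 and 16.2 FPKM in knockout brain.

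**Figure D3:**
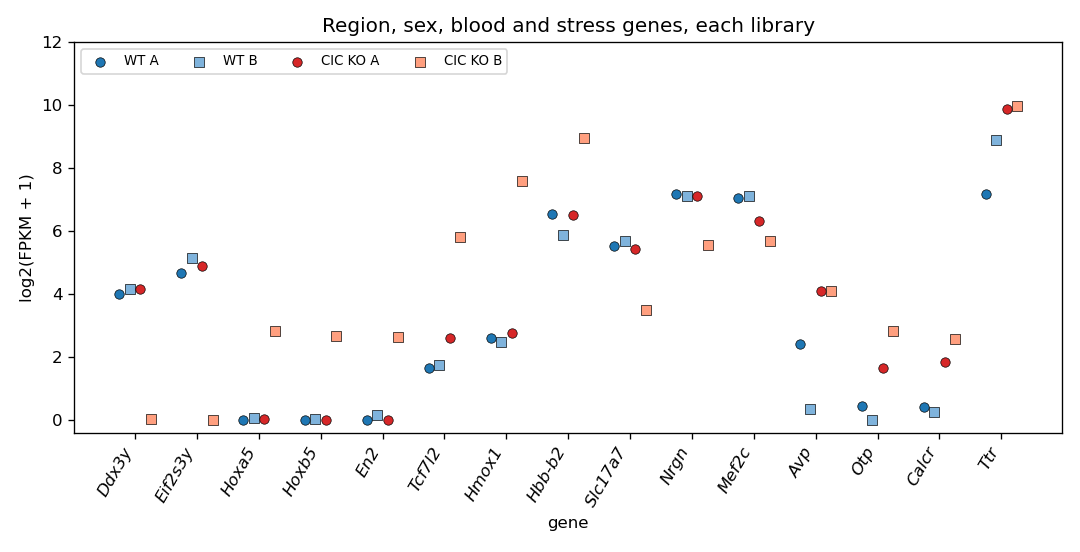
log2(FPKM + 1) of Y-linked, regional, stress, globin, cortical, hypothalamic and choroid plexus genes in each of the 4 libraries; circles are replicate A, squares replicate B, blues WT and reds CIC knockout. Ddx3y is at 0.0173 FPKM and Hoxa5 at 6.09 FPKM in knockout B alone, while Mef2c is lower and Avp higher in both knockout libraries than in both WT libraries.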

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

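Leaving out the rows with a listed 0, library quality weights and a pseudocount of 1 for the added marker lists were chosen after seeing the data; the other alternatives were planned. Cic stayed lower in knockout brain under each alternative run for it, from -1.45 to -1.199, and passed the threshold only without knockout A (-1.24) or knockout B (-1.45); leaving out single libraries gave -1.45 to -1.24. Main counts were 3 genes higher and 3 lower, and 7 lists higher and 8 lower. Genes called higher numbered 1 with a pseudocount of 0.1 (Etv4), 1 with no filter (Hmx3) and 0 without the rows listed at 0. In the last setting 0 were also called lower, since the 3 smallest p-values had been removed. No gene was then left for Fisher's exact test of the CIC target list. Leaving out single libraries gave 1 to 2269 genes higher and 3 to 2036 lower; both extremes on the high side came without knockout A. Without either knockout library the spread came from the WT pair alone and the lone knockout library was assumed to vary like it. Without knockout B, 16 were higher and 11 lower. Etv4, Spred3 and Mid1 kept log2 changes of 2.54, 1.99 and 2.34 without WT A and of 2.47, 2.15 and 2.33 without WT B. Their SEs rose in both fits, since the spread then came from the knockout pair alone. Members of the CIC target list among genes called higher numbered 0 with no filter (Fisher's exact p = 1) and 0 to 11 with single libraries left out, 0 without WT A and without WT B, where the pooled spread came from the more variable knockout pair.

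Lists called higher numbered 3 with no filter, 5 with a mean FPKM of 5 or more and 0 with an estimated correlation; lists called lower numbered 5 with a pseudocount of 0.1, 4 with no filter, 3 with a mean FPKM of 5 or more, 6 with libraries rescaled to a median log2 ratio of 0, 7 with library quality weights and 0 with an estimated correlation. With single libraries left out, 6 to 10 lists were higher and 4 to 8 lower. The CIC target, cortical layer and choroid plexus lists kept their call under each alternative except the estimated correlation; for the CIC target list camera's adjusted p otherwise ran from 2.76e-13 to 0.000628. With a mean FPKM of 5 or more, the medians of the cell cycle list (-0.047) and the blood list (-0.053) changed sign, and the cause was not tested.

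Medians or gene differences that changed sign when single libraries were left out ranged from -0.052 to 0.080 for neural stem cell genes, -0.16 to 0.31 for cell cycle genes, -0.36 to 0.35 for interneuron genes, -0.016 to 0.19 for endothelial genes, -0.75 to 2.33 for blood genes, -0.025 to 0.23 for interferon genes and -3.44 to 0.040 for sex-linked genes. Among single genes the ranges were -1.42 to 0.031 for Slco1c1, -6.57 to 1.23 for the Hba-a1 locus with the larger WT values, -0.00047 to 2.80 for Hoxa5, -0.013 to 2.66 for Hoxb5, -4.89 to 0.0038 for Eif2s3y, -4.06 to 0.093 for Ddx3y, -0.16 to 0.12 for Ccnd1, -0.17 to 0.54 for Etv1, -0.28 to 0.10 for Phlda1 and -0.25 to 0.00070 for Spry2. Depth limits low genes most, and no interval can be given without counts.

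With the replicate letter as a block, 4 genes were higher and 3 lower, Vgf being added (adjusted p = 0.0212), and the pericyte list was also called (adjusted p = 0.0427). Deviations of the A libraries from their group means correlated at -0.0135 across genes. With only 2 pairs, and with knockout B apart from the other libraries, this cannot decide whether the letters pair the samples. Alternatives for count tables, for the authors' own tests and for random lists were not run because the table holds FPKM per library.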

Other observations

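The genes in this and the next paragraph were chosen after their values were seen, and apart from Etv4, Spred3 and Mid1 none of them passed the test over all genes. In 43 genes every knockout library was at least 2-fold above every WT library, and in 5 at least 2-fold below, rows with a listed 0 left out. Genes on the low side beside Cic included Inhba, which encodes an activin subunit (4.35 and 3.82 FPKM in WT, 1.84 and 1.61 FPKM in knockout brain), Dio2, the thyroid hormone activating deiodinase (4.05 and 4.03 FPKM against 1.93 and 1.63 FPKM), and Ly6g6e (2.23 and 2.40 FPKM against 1.11 and 0.252 FPKM).

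No shared theme was tested on the genes of the high side themselves. A larger share of hypothalamus, weighed below for Avp, stays open for some of them too. Genes on the high side included the galanin gene Gal (1.73 and 0.971 FPKM in WT, 4.13 and 5.10 FPKM in knockout brain). Trh had 0.972 and 1.33 FPKM against 2.90 and 3.01 FPKM. Others were Magel2 of the Prader-Willi region (4.03 and 3.27 FPKM against 8.06 and 11.5 FPKM), Asb4 (1.19 and 1.00 FPKM against 4.99 and 6.80 FPKM), Calcr, the calcitonin receptor gene (0.340 and 0.1996 FPKM against 2.64 and 4.96 FPKM), and Irs4 (0.719 and 0.337 FPKM against 3.42 and 4.22 FPKM). Ecel1, a neuronal endopeptidase gene, had 5.55 and 4.65 FPKM against 13.3 and 12.2 FPKM, and the p53-inducible Pmaip1 had 0.478 and 0.460 FPKM against 1.47 and 1.62 FPKM. Fam98c, the neighbour of Spred3 on chromosome 7 (29937529 to 29941229), is not among the 43 and had 8.62 ± 0.0643 FPKM in WT and 17.4 ± 0.626 FPKM in knockout brain (SD, n = 2 each). Within 10 Mb of Cic, 10 of 240 genes (4.17%) differed at least 1.5-fold, against 542 of 12463 (4.35%) elsewhere. Spred3 and Apoe are among these 10, and a share over the whole window cannot speak for single genes.

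In the paragraphs that follow, the tests of animal sex and of the exact zeros were chosen only after the result was seen. Markers for these tests were listed before their own values were seen: 17 caudal genes, 9 of which the fixed lists also hold, 18 hypothalamic genes and 13 cortical genes. A mean of 0.5 FPKM or more over the 4 libraries was reached by 8, 9 and 13 of them. Limits for reading the log2 ratios of these markers were also set beforehand, without naming a pseudocount. The ratios were taken with a pseudocount of 0.1, and again with the pseudocount of 1 used elsewhere once the result was seen. With 0.1 alone the hypothalamic markers would have counted for a larger share of hypothalamus; asking both pseudocounts to give the same answer was chosen after the result was seen.

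Knockout B stood apart from the other 3 libraries in hindbrain, blood and Y-linked genes. More blood as the whole cause is argued against, since the caudal markers were above knockout A by a median log2 ratio of 3.66 with a pseudocount of 0.1, or 1.45 with 1, while pan-neuronal genes were at -0.16 with either. Midbrain, hindbrain or spinal tissue in that library may account for much of the regional part: 17 of 17 caudal markers, a share of 1, were highest in knockout B, the most abundant being Gbx2 (7.66 FPKM), Gata2 (4.14 FPKM) and Hoxb3 (3.55 FPKM). Knockout A, of the same genotype, had a median log2 ratio of 0 to WT, although 5 of the 17 were above both WT libraries there too, among them Gbx2 (1.90 FPKM against 0.816 and 0.728 FPKM). Sex and library cannot be told apart, since no other library lacked Y-linked RNA; of the 201 genes at least 2-fold apart between knockout A and B, 7 (3.48%) lie on X or Y.

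Exact zeros in well-expressed genes, including Prkar1b, Actr3 and Papd5 in both knockout libraries, may be failed estimates of the quantification. In knockout A both alpha-globin Hba-a1 loci were listed at 0 while the beta-globin rows Hbb-b2 and Beta-s had 90.0 and 343 FPKM; Hbb-b1, whose row overlaps Hbb-b2, was near 0 there (0.000919 FPKM) and in WT A (0.000743 FPKM). Of the 13 affected rows, 4 had a zero in a WT library. A real loss of these 3 RNAs in CIC knockout brain stays open, because 10 of the 13 rows showed zeros in another pattern and a listed 0 therefore carries no information on the level.

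Mef2c and the cortical layer list were lower, and Avp higher, in both knockout libraries. For Mef2c in knockout A, the limits set beforehand counted against a smaller share of cortex as the whole cause. With a pseudocount of 0.1 the 13 cortical markers had a median log2 ratio to WT of -0.29 (lower quartile -0.49, lowest -0.64). Mef2c was at -0.75. The lowest marker came near this value and the reading rests on a single library, so a smaller share of cortex stays open there. It also stays open for Mef2c in knockout B (-1.40), where the markers spread widely (median -0.35, lower quartile -0.68). The same holds for the layer list, whose medians (-0.23 and -0.34) are near those of the markers in both libraries. A larger share of hypothalamus also stays open for Avp and for other hypothalamic genes that were higher. Of 18 hypothalamic markers 11 were above both WT libraries in knockout A and 17 in knockout B. Their median ratios were 0.56 in knockout A and 1.69 in knockout B with a pseudocount of 0.1. With a pseudocount of 1 they were 0.17 and 0.58, so that the reading turns on the scale. What stays open cannot be told apart from a change in gene activity within these regions on loss of CIC, which was not tested.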
